A study of Caenorhabditis elegans with 2 samples.

How the data were processed

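Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on whole Caenorhabditis elegans larvae of the fourth larval stage, with both sexes pooled. Per the labels, the animals carried an integrated construct with the forkhead gene fkh-10 joined to TY1, EGFP and FLAG tags, together with a copy of unc-119. The labels name 2 biological replicates, both of 1 group, and a selected fragment size of 150 to 350 bp. With 1 group there was no comparison between conditions, and the comparisons made here were between replicates, between region lists, and between regions or genes within the lists.

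The authors deposited 8 lists of regions, 4 on each of the genome builds ce11 and ce10. Per the labels and the file descriptions, 1 list per build holds the regions past the authors' irreproducible discovery rate threshold over both replicates, called IDR regions here. The other lists hold relaxed calls, background included, for the pooled replicates, for replicate 1 and for replicate 2. In the deposited lists each region has a signal value and a −log10 q-value, in the narrowPeak column order. The signal is the authors' enrichment relative to a control library; its scale, the aligner, the peak caller and their thresholds are not given in the sources used here. The deposited −log10 values reached a ceiling shared by 76.1% of the IDR regions, so regions were ranked by the authors' signal only. Reads were not analysed here and the depth of each library is unknown; shares of regions carry 95% Wilson intervals, which cover counting error only. Signal values were used to rank and describe regions within a list and were not compared in size between lists of different make.

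All positions are on ce11, counted from 1. The region ends lay within the chromosome lengths of the WBcel235 reference, which is the sequence of ce11, and its Ensembl release 115 annotation (19973 protein-coding genes) gave gene positions. The ce10 lists were used for counts, chromosome shares and replicate overlap alone, with no conversion of positions. Regions in separate lists were taken as the same site where their summits lay within 100 bp. The background for IDR regions was the 17154 pooled relaxed regions with no IDR summit within 100 bp. Of the 2253 IDR regions, 98.8% had a pooled summit within 100 bp, and 902 had the same start and end as a pooled region but none the same signal, so the IDR list was not a plain subset of the pooled list.

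A promoter was the interval from 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcript start. The other locations were assigned in the order noncoding gene within 200 bp, exon, intron and intergenic. Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 5 locations, the 10 motifs and the 27 gene lists. The share on chromosome X was also compared with the pooled list by an exact binomial test. Circular shifts of the regions along their chromosomes (1000 shifts, seed 1) gave the overlap and the promoter share of shifted positions. Motifs were sought on either strand within 100 bp of the summit. GC matching drew background windows from the same 5-point bins of GC content. For the gene lists, a gene was bound when an IDR summit lay in its promoter window, and the background was the genes with a relaxed or IDR summit in that window. Protein-coding genes were the background of lists made from gene symbols, and all annotated genes except piRNA genes that of lists made from gene types. A run was a series of regions with gaps of at most 2000 bp and a length of at least 30 kb. The runs examined further were those of the pooled list that overlapped such a run in each replicate list.

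The genes and regions named were set before the data were examined: the 25 IDR regions with the highest signal, with the genes whose promoter window held the summit or else the nearest gene; fkh-10 and unc-119; up to 4 members with the highest signal of each list with an adjusted p under 0.05 or with 5 or more bound members; and all bound members of the forkhead and cilium lists. A region that this rule names among the chemoreceptor genes is left out here by request. The main tests, the gene lists and the 10 motifs were set at the same time. The recruitment motif was chosen after the strong X regions were seen but before it was counted, several further tests were chosen after their results were seen, and tests planned for GC content on chromosome X and for the runs at gene lists were replaced because they could not decide. Replicate files were compared before use, and 0 regions had the same position and signal in both. The steps were tested on simulated data. A planted overlap of 60.0% of 2253 regions was recovered as 60.0%. A planted gene list among 6257 genes was called in 100% of 20 simulations, with 0.455% of unchanged lists called. In these simulations genes were set as bound independently of each other, and lists made from gene types were left out. The rate of false calls therefore does not cover regions shared by neighbouring genes. A planted gain of 10 percentage points in motif share over 2000 windows was recovered as 10. All 40 regions of a planted run, placed in a list with no other regions, were found. These checks cover the code and not the error rates in the real lists.

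The alternatives were each replicate left out (the 2253 strongest relaxed regions of the other replicate in place of the IDR regions), the 2253 strongest pooled regions, the 1126 strongest IDR regions, the regions within 50 kb of fkh-10 and unc-119 left out, other overlap rules, promoter windows, motif windows and backgrounds, and the ce10 lists. Leaving out the runs of regions on chromosomes I and X and GC matching within promoters were added after the data were seen. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Control libraries, read alignments and signal tracks were not used here.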

Results

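FKH-10 is a forkhead transcription factor, a class of proteins that bind DNA through a winged-helix domain. Per its labels, the series measured where an EGFP-tagged FKH-10 lay on the genome of fourth-stage larvae of the nematode Caenorhabditis elegans, by ChIP-seq in 2 biological replicates of whole animals. The deposited lists held 2253 IDR regions, 19381 pooled relaxed regions, 30000 relaxed regions for replicate 1 and 28886 for replicate 2. Depth in reads was unknown, so the precision of each region's signal could not be stated, and the spread between the replicates is given in its place.

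The construct genes were examined first, as a check of the labels. fkh-10 (WBGene00001442, chromosome I, 10163475 to 10165132, minus strand) had 0 regions within 20 kb in the IDR, pooled, replicate 1 and replicate 2 lists. The nearest pooled summit lay 20.6 kb from the gene and the nearest IDR summit 32.1 kb. unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), a neuronal gene used as the selection marker of such constructs, had 7 pooled, 3 replicate 1 and 8 replicate 2 regions with the summit inside the gene, and 12, 16 and 14 within 20 kb. The IDR list had 1 there, with its summit at 10903338, with a signal of 77.0 and rank 565 of 2253. The same site ranked 522 in replicate 1, with a signal of 35.5, and 1063 in replicate 2, also with a signal of 35.5. No region at fkh-10 thus marked the construct that the labels name, and whether the regions at unc-119 came from it was not tested. The libraries are therefore called the libraries labelled FKH-10 below.

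Dense runs of regions lay elsewhere, and were picked out after their values were seen. On chromosome I, 70 pooled regions filled 40.3 kb from 14719414 to 14759726, or 17.4 regions per 10 kb against 1.25 in the 20 kb on either side. The run spanned 14 protein-coding genes, among them pbs-5, a proteasome subunit, hmp-2, a beta-catenin of cell junctions, mtx-1 and dnj-12. On chromosome X, 51 pooled regions filled 35.7 kb from 16343857 to 16379585, or 14.3 per 10 kb against 2.5 beside it, across taf-3, the nuclear hormone receptor gene nhr-28, the acetylcholinesterase gene ace-1 and sur-7. Both were kept because they overlapped a run in each replicate list, so their presence in both replicates was set by the rule. Within the bounds above, replicates 1 and 2 had 73 and 70 regions on chromosome I and 55 and 60 on chromosome X. In replicate 2 the run on chromosome I was longer, from 14715145 to 14769335, with 81 regions. The IDR list held 32 regions of the first run and 14 of the other. A further run of 33768 bp on chromosome IV, from 7026087 to 7059854, was found in the pooled list and in replicate 1 but not in replicate 2. Replicate 1 alone also had runs on chromosome II, from 10537041 to 10568427 (29 regions) and from 6818051 to 6848683 (27 regions), and the first of them holds the strong region at cdc-48.1.

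**Figure D1:**
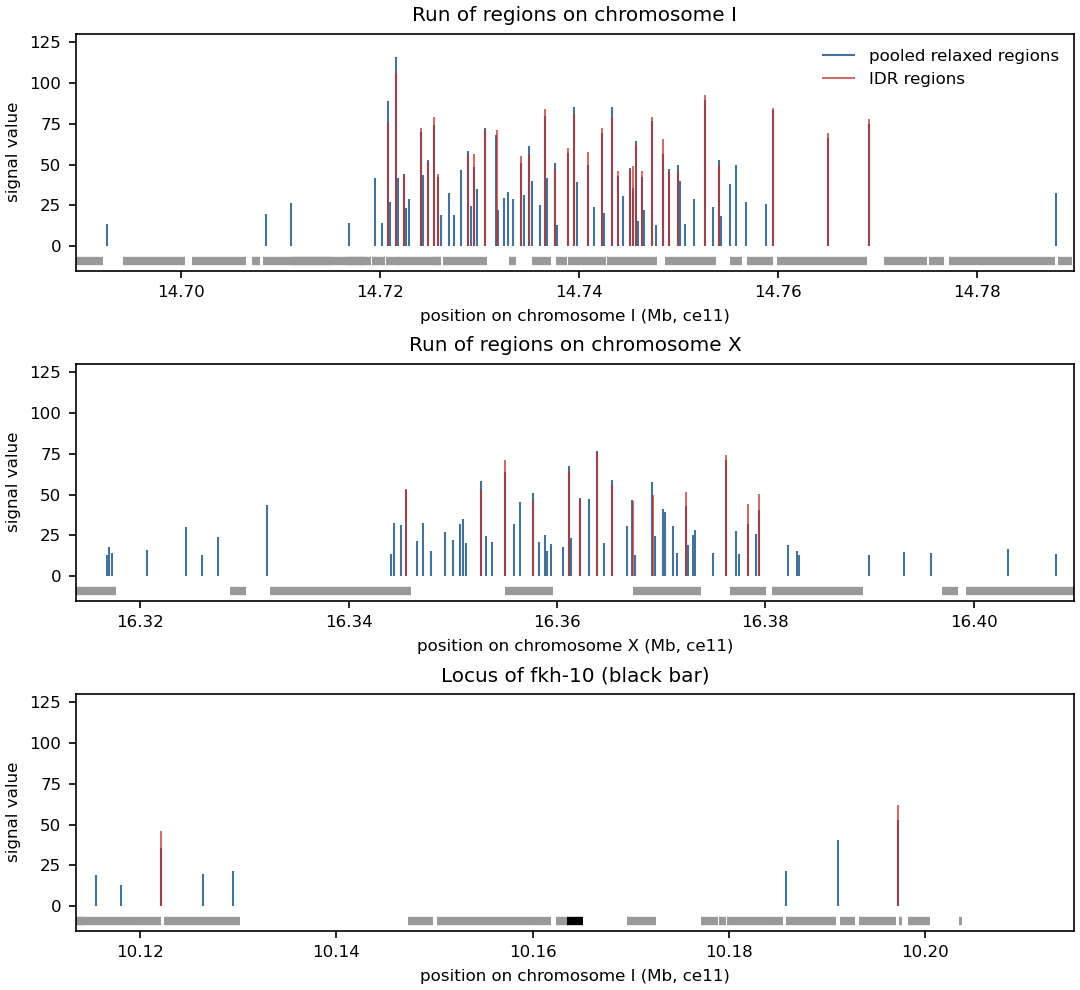
Position on the chromosome (Mb, ce11) against the authors' signal value for pooled relaxed regions (blue) and IDR regions (red) around the runs on chromosomes I and X and around fkh-10, with protein-coding genes as grey bars and fkh-10 in black. The runs hold 70 and 51 pooled regions, and fkh-10 has 0 within 20 kb.

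The strongest regions lay at ribosomal protein genes and, on chromosome X, away from promoters. The region with the highest signal, 304, was in the promoter of rpl-3, a protein of the large ribosomal subunit (chromosome III, 3867471 to 3867664, summit 276 bp upstream of the start). It ranked 1 in both replicates, with signals of 145 in replicate 1 and 163 in replicate 2. Next came the promoters of rpl-20 (shared with Y17G9B.5; chromosome IV, 4749982 to 4750169, signal 260.5), cdc-48.1, an AAA ATPase of protein quality control (chromosome II, 10563478 to 10563644, signal 251), and rpl-15 (shared with K11H12.8; chromosome IV, 654854 to 655008, signal 239). The fifth, with a signal of 226, lay at H41C03.3 and over sls-2.1, a gene for a spliced leader RNA (chromosome II, 5844596 to 5844985). Of the 25 strongest regions 7 were at ribosomal protein promoters, including those of rpl-12 (shared with lin-54), rps-12 (shared with ska-3), rpl-11.2 and rpl-35. Others of the 25 were at iff-2, encoding translation factor eIF5A, with a second region in an exon there, at cox-5B, a cytochrome c oxidase subunit, and at hsp-1, a cytosolic Hsp70. The promoters of puf-9, egg-5 and the pair K01G5.10 and tasp-1 completed those at genes. All 25 were among the 2253 strongest regions of each replicate, although the region on chromosome X at 13700886 ranked 3 in replicate 1 and 497 in replicate 2.

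Chromosome X held 11 of the 25 strongest regions, and 9 of these were away from promoters, against 1 of 14 on the autosomes. The strongest of them were intergenic, at 11094037 to 11094426 (signal 214, nearest start W02H3.3 at 3954 bp) and at 12362976 to 12363365 (signal 210.5, nearest start F19H6.5 at 1733 bp). The next had its summit in an intron at 6296557 (signal 199, nearest start cest-16 at 3385 bp). The remaining 6 had summits at 13700886 (nearest K02D3.1), 9465846 (ZK899.6), 806675 (gtr-1), 16056565 (T27A8.7), 2997093 (Y41G9A.17) and 16682147 (F22H10.2), with signals from 193 to 175. In the whole IDR list, 530 of 2253 regions (23.5%, interval 21.8 to 25.3) lay on chromosome X, against 20.1% of the background (Fisher's exact test, p = 0.000158; exact binomial test against the pooled list, p = 0.000381). The density was 29.9 regions per Mb on chromosome X, and from 14.1 on chromosome V to 26.6 on chromosome III among the autosomes. The X excess was 3.46 percentage points.

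The replicates shared most of their strong regions, while the signal at a shared region varied. Of the 2253 strongest regions of replicate 1, 1286 (57.1%, interval 55.0 to 59.1) had a summit of the 2253 strongest of replicate 2 within 100 bp, against a mean of 0.480% and at most 1.11% after circular shifts. Of the IDR regions, 71.1% were among the 2253 strongest of replicate 1 and 78.6% among those of replicate 2, and 93.1% and 95.9% were in the relaxed lists. The IDR list was derived from both replicates, so these shares are descriptive. Whether each IDR region had to be found in both replicates is not known. With 1 bp of overlap, 98.9% of them met a relaxed region of replicate 1 and 99.7% one of replicate 2. At the 2013 IDR regions found in both relaxed lists, Spearman's rho was 0.408 and Pearson's r of the log2 signal 0.383, across regions, which are not independent replicates. The median signal was 25.9 in replicate 1 and 34.2 in replicate 2, and the log2 ratio between them had an SD of 0.72. At fkh-9, for example, the signal was 20.3 in replicate 1 and 48.9 in replicate 2. At nhr-49 it was 48.9 and 18.9.

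**Figure D2:**
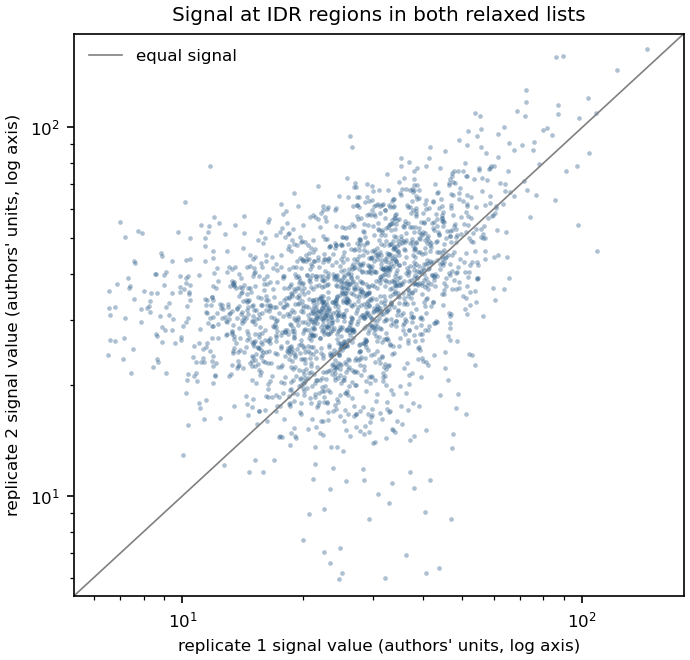
Authors' signal value in replicate 1 (x axis, log) and replicate 2 (y axis, log) at the 2013 IDR regions found in both relaxed lists, with a line of equal signal. Spearman's rho was 0.408, and the medians were 25.9 and 34.2.

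Promoters held 1099 of the IDR regions (48.8%, interval 46.7 to 50.8) against 31.9% of the background (Fisher's exact test, here and below, with Benjamini-Hochberg adjustment; adjusted exact p = 3.23e-54). In shifted positions the mean was 25.6% and the highest 28.9%. Regions at noncoding genes were also more frequent, 11.98% against 5.53% (adjusted exact p = 3.67e-27). Exons held 2.13% against 14.4% (adjusted exact p = 8.26e-82) and introns 15.002% against 25.6% (adjusted exact p = 1.03e-30), both lower. Intergenic regions made up 22.1% against 22.6%, which did not pass the test (adjusted exact p = 0.629). The promoter regions marked 1395 of the 6260 protein-coding genes with a relaxed or IDR region at the promoter, 22.3%. Neighbouring genes shared many of them: 321 promoter regions lay at 2 or more genes, as at rpl-12 and lin-54, so the target among them is not assigned.

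The forkhead consensus RTAAAYA was less frequent at IDR summits than in the background, and this direction depended on GC content. It occurred within 100 bp of 315 IDR summits (13.98%, interval 12.61 to 15.5), against 18.97% of background windows (Fisher's exact test, adjusted exact p = 1.02e-08). The IDR windows were richer in GC, with 42.8% ± 7.08 (SD, 2253 windows) against 36.2% ± 8.40, and against GC-matched background windows the consensus was at 12.8% (Fisher's exact test, p = 0.274), a difference of 1.15 percentage points in the other direction. The difference from the unmatched background was 6.13 percentage points above the median of 100 permutations of the consensus letters, which was -11.1 (permutation test over the shuffles, p = 0.0396). No direction was therefore assigned to the consensus. The narrower form GTAAACA, bound by the forkhead factor DAF-16, was at 3.60% against 2.69% (adjusted exact p = 0.0244) and against 2.17% of GC-matched windows (adjusted exact p = 0.0140). It was nearly as frequent 300 to 500 bp to one side of the same summits, at 3.33%, and was at 3.00% of the 300 strongest IDR regions. These 2 differences were not tested.

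Other motifs stood further from the background. The GAGA repeat GAGAGAG was at 20.1% of IDR summits against 5.57% (adjusted exact p = 3.36e-102), and 9.37% with GC matching (adjusted exact p = 1.49e-23). The GATA factor site TGATAA (7.19% against 14.9%, adjusted exact p = 9.91e-26) and the homeodomain site TAATTA (3.55% against 9.44%, adjusted exact p = 3.53e-24) were less frequent, and stayed so with GC matching, at 10.4% (adjusted exact p = 0.000603) and 6.26% (adjusted exact p = 0.000158) of matched windows. The RNA polymerase III B box was at 13 summits, 0.577% against 0.163% (adjusted exact p = 0.000852), and 0.133% with GC matching (adjusted exact p = 0.0421). The SP1-type site CCCGCCC was at 2.35% against 1.29% (adjusted exact p = 0.000370), but 2.04% with GC matching (adjusted exact p = 0.542). The AP-1 site (2.26% against 1.84%, adjusted exact p = 0.202), the E-box (3.82% against 3.29%, adjusted exact p = 0.205) and the X-box core (0.311% against 0.525%, adjusted exact p = 0.205) did not pass the test. With GC matching the E-box turned direction, at 5.10% of matched windows (adjusted exact p = 0.0718).

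**Figure D3:**
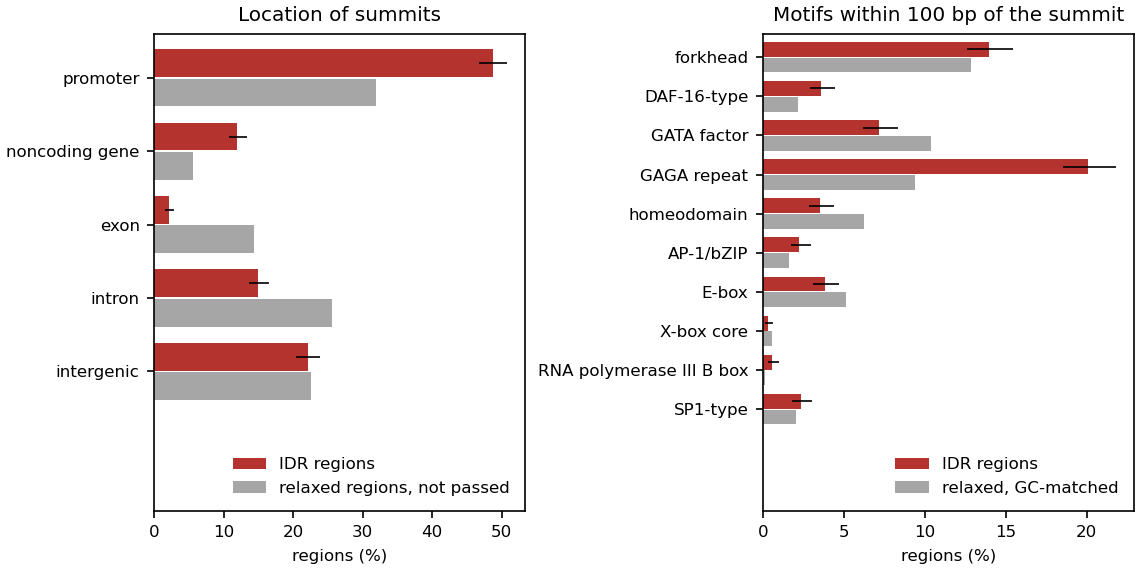
Share of regions (%) by location of the summit (left) and with each motif within 100 bp of it (right), for IDR regions (red, with 95% Wilson intervals) and for relaxed regions that did not pass (left, grey) or GC-matched ones (right, grey). Promoters held 48.8% against 31.9%, and the GAGA repeat was at 20.1% against 9.37% of matched windows.

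Genes of protein synthesis, protein folding and respiration were bound more often than other genes. Of 74 ribosomal protein genes with a relaxed or IDR region, 59 (79.7%, interval 69.2 to 87.3) had an IDR region at the promoter, against 21.6% of other genes (Fisher's exact test, adjusted exact p = 1.78e-24), led by rpl-3, rpl-20, rpl-15 and rpl-12 with signals from 304 to 201. Of 24 genes of mitochondrial respiration and ATP synthase 14 were bound (58.3%, adjusted exact p = 0.000753), led by the cytochrome c oxidase subunit genes cox-5B (signal 171) and cox-5A (158), the ATP synthase gene atp-1 (155) and cox-6B (133). Of 35 heat shock protein and chaperone genes 19 were bound (54.3%, adjusted exact p = 0.000322), with hsp-1 (165), the chaperonin subunit genes cct-8 (138) and cct-7 (135) and the mitochondrial chaperonin gene hsp-60 (133) at the top. Translation factors had 14 of 31 genes bound (45.2%, adjusted exact p = 0.0146). Besides iff-2 these included the elongation factor genes eef-1A.2 (signal 149.9), eef-2 (131) and eef-1A.1 (122). In each replicate these regions were present: at eef-2 the signal was 51.5 in replicate 1 and 61.3 in replicate 2, and at hsp-1 53.97 and 109.

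Of 23 pan-neuronal synaptic genes 12 were bound (52.2%, adjusted exact p = 0.00727), among them egl-21, a carboxypeptidase of neuropeptide processing (signal 102), unc-18, of synaptic vesicle fusion (96.9), rgef-1 (95.7) and syd-2, a liprin of the presynaptic zone (88.6). Genes for snoRNAs, which guide the modification of ribosomal RNA, had 60 of 168 bound (35.7% against 22.4%, adjusted exact p = 0.000753). The strongest of these regions, at C06A1.9, K11H12.12, K11H12.13 and F54E7.10, were those at the promoters of cdc-48.1, rpl-15 and rps-12, and 18 of the 60 genes were bound by a region outside protein-coding promoters. Chemoreceptor genes were bound less often, 8 of 179 (4.47% against 22.8%, adjusted exact p = 4.16e-10). Those bound included sri-5 (signal 95.3) and srr-10 (56.0). Neuropeptide and insulin genes were likewise bound less often, 2 of 42 (4.76%, adjusted exact p = 0.0146): ins-39, with a signal of 148, and flp-22, with 58.2.

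Some of these calls were lost, or became smaller, when the window, the rule or the replicates changed. Ribosomal protein genes stayed called, but the excess over other genes fell from 58.1 to 35.3 percentage points without replicate 2 (41 of 74) and to 33.4 with a region assigned only to its nearest start (37 of 74). Translation factors did not pass with the strongest regions of replicate 1 alone, without replicate 2 (11 of 31, adjusted exact p = 0.124), with the 1126 strongest IDR regions (8 of 31, adjusted exact p = 0.0852), with a region assigned only to its nearest start (10 of 31, adjusted exact p = 0.143) or with the promoter narrowed to 500 bp upstream and 100 bp downstream (12 of 28, adjusted exact p = 0.165). Neuropeptides and insulins did not pass under the same changes (3 of 42, 1 of 42, 2 of 42 and 0 of 17; adjusted exact p = 0.0992, 0.253, 0.143 and 0.0570). With the nearest start only, chaperones (8 of 35, adjusted exact p = 0.702) and snoRNA genes (24 of 168, adjusted exact p = 1) did not pass either. With the narrowed promoter neither snoRNA genes (31.3%, adjusted exact p = 0.299) nor pan-neuronal genes passed (adjusted exact p = 0.0744), although the pan-neuronal share hardly moved, at 10 of 20 against 12 of 23. tRNA genes passed without replicate 2 (85 of 275, adjusted exact p = 0.00184; range over the alternatives 1.46e-06 to 1) and had 56 of 274 bound without replicate 1, below the share of other genes. They also passed with the promoter widened to 2000 bp upstream and 500 bp downstream (98 of 353, adjusted exact p = 0.0245), as did nuclear hormone receptors, bound less often (13 of 116, adjusted exact p = 0.0178). With all annotated genes as background, tRNA genes (77 of 612, adjusted exact p = 1.46e-06), proteasome (8 of 33, adjusted exact p = 0.00478) and vacuolar ATPase genes (6 of 20, adjusted exact p = 0.00513) passed as bound more often and cuticle collagens as bound less often (4 of 173, adjusted exact p = 0.0232).

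**Figure D4:**
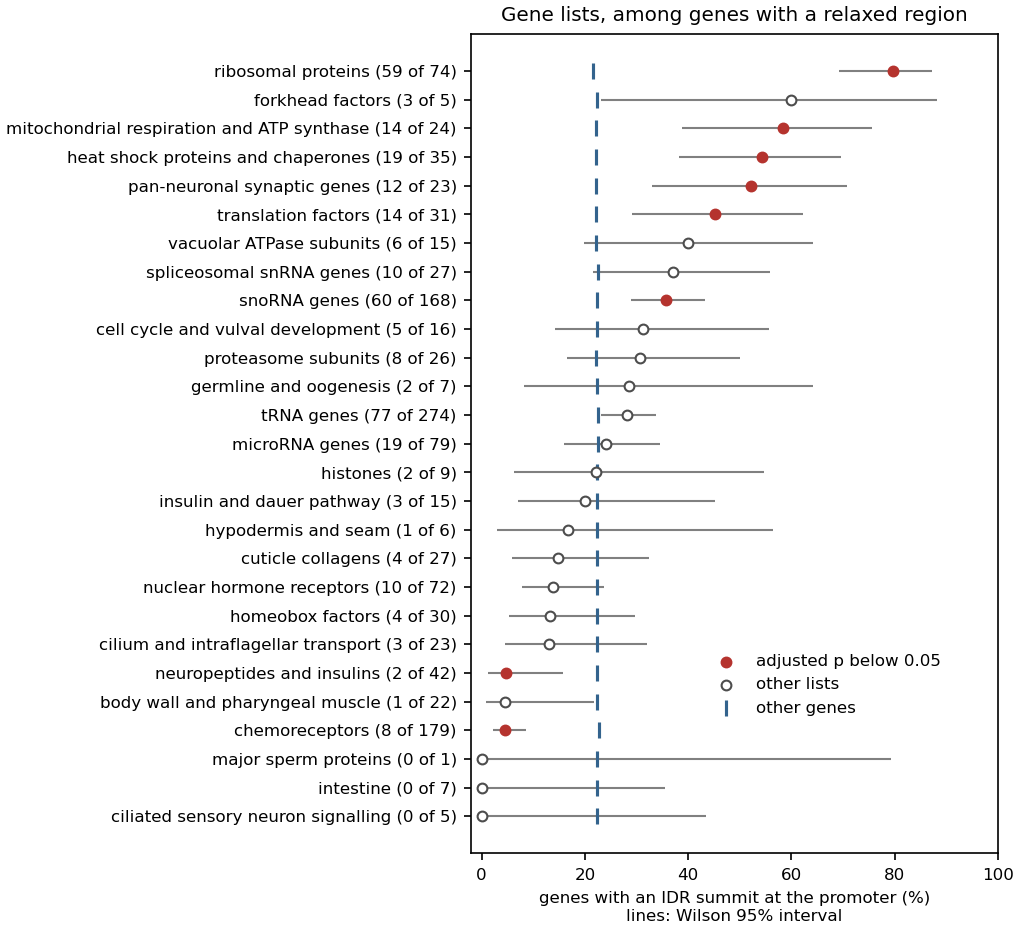
Share of genes with an IDR summit at the promoter (%, points with 95% Wilson intervals) for each of the 27 lists, with the share among other genes of the background (blue ticks) and the bound and background gene counts beside each name. Filled points mark the 8 lists with an adjusted p under 0.05, from 59 of 74 ribosomal protein genes to 8 of 179 chemoreceptor genes.

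Forkhead factor genes were few: 3 of 5 with a relaxed or IDR region were bound (adjusted exact p = 0.189). They were fkh-9 (chromosome X, signal 76.4), fkh-7 (chromosome IV, 65.8) and daf-16, the FOXO factor of insulin signalling (chromosome I, 44.5). The daf-16 summit had a match in replicate 1 (signal 21.9) but none within 100 bp in replicate 2. Cilium genes had 3 of 23 bound (13.04%, adjusted exact p = 0.639): klp-11, a kinesin-II motor subunit (signal 105), and the intraflagellar transport genes ift-81 (56.3) and dyf-1 (41.8). Genes of ciliated sensory neuron signalling had 0 of 5 bound (adjusted exact p = 0.763). Nuclear hormone receptor genes had 10 of 72 (adjusted exact p = 0.199), led by nhr-48 (88.3), nhr-49 (73.98), nhr-28 (70.9), which lies in the run on chromosome X, and nhr-14 (65.5). Homeobox genes had 4 of 30 (adjusted exact p = 0.503).

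Proteasome subunit genes had 8 of 26 bound (adjusted exact p = 0.560), with rpn-3 at a signal of 93.6 and pbs-5, inside the run on chromosome I, at 75.4 (26.7 in replicate 2, with no match within 100 bp in replicate 1), followed by rpn-11 (56.0) and rpn-13 (47.8). Vacuolar ATPase genes had 6 of 15 (adjusted exact p = 0.227), led by vha-15 (73.99), vha-8 (67.5), vha-12 (56.1) and vha-13 (52.8). Cell cycle and vulval genes had 5 of 16 (adjusted exact p = 0.560), with the Rb gene lin-35 (84.7), the E2F gene efl-1 (80.3), lin-28 (78.4) and cye-1 (55.3). The snRNA genes had 10 of 27 (adjusted exact p = 0.213), and the top 3, sls-2.1 (226), sls-2.4 (173, in the region at egg-5) and sls-2.2 (141), encode spliced leader RNAs and not spliceosomal snRNAs; the next was F38E11.11 (92.5). tRNA genes had 77 of 274 (28.1% against 22.5%, adjusted exact p = 0.100), with the highest signals at WBGene00008135 (95.6), WBGene00022947 (93.5) and the pair WBGene00023111 and WBGene00023110, which share a region (90.8). MicroRNA genes had 19 of 79 (adjusted exact p = 0.924), with cel-mir-354 (151), cel-mir-5549 (122, in the region at eef-1A.1), cel-mir-2 (119.97) and cel-mir-56 (114.9).

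The remaining lists were bound at low counts that did not pass the test, and several moved when 1 replicate was left out. Body wall and pharyngeal muscle had 1 of 22 genes bound (adjusted exact p = 0.112), but 3 of 22 without replicate 1 (adjusted exact p = 0.633) and also without replicate 2 (adjusted exact p = 0.748). Histones had 2 of 9 (adjusted exact p = 1), 1 of 9 without replicate 1 and 5 of 9 (55.6%) without replicate 2 (adjusted exact p = 0.0738), which turned the difference from other genes from -0.0622 to 35.1 percentage points. The insulin and dauer pathway had 3 of 15 (adjusted exact p = 1), and 4 of 15 without replicate 1 and also without replicate 2, above the share of other genes. Hypodermis and seam had 1 of 6 (adjusted exact p = 1), 0 without replicate 1 and 2 without replicate 2, and germline and oogenesis 2 of 7 (adjusted exact p = 0.805), and 1 without replicate 2. Intestine had 0 of 7 (adjusted exact p = 0.560), cuticle collagens 4 of 27 (adjusted exact p = 0.658) and major sperm proteins 0 of 1 (adjusted exact p = 1). Whole animals were used, so no region was assigned to a cell type.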

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

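Leaving out the runs and GC matching within promoters were chosen only after the results were seen. The excess on chromosome X and at promoters and the count of 2253 regions kept their direction and side of the threshold, or stayed within 1.5 times the main count, under each alternative but the 1126 strongest IDR regions, which is a smaller count by construction. The X excess lay between 2.66 and 4.29 percentage points and the promoter excess between 14.6 and 16.3 without replicate 1 or 2. The forkhead consensus, at -4.99 percentage points against the background, turned to 1.15 with GC matching (Fisher's exact test, p = 0.274) and 1.64 with GC matching within promoters (exact p = 0.299). Its letter shuffles had a median of -11.1 against the same background, so the consensus stood 6.13 above them while still below the background (permutation p = 0.0396). A higher GC content of the IDR windows goes with the change under GC matching, and the other 9 alternatives kept the lower share.

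Looser rules for a shared region raised the overlap. With 1 bp of overlap or with 50% reciprocal overlap, the share of IDR regions among the strongest of replicate 1 was 76.0% or 74.4% and of replicate 2 82.6% or 81.003%. In the relaxed lists it was 98.9% or 97.2% and 99.7% or 98.7%. The overlap of the strongest regions between replicates was 66.0% or 62.8%. The correlation of signal was 0.245 among the 1126 strongest IDR regions, where the range of signal is narrower by construction. Of the 8 lists called, 4 were called with a promoter of 500 bp upstream and 100 bp downstream, and 4 with the nearest start only, where the snoRNA difference was -0.210 percentage points (adjusted exact p = 1); the cause was not tested. Ribosomal proteins, respiration genes and chemoreceptors stayed called under all 10 alternatives. Of the 269 values of single lists under alternatives, 227 kept their direction and side of the threshold, 11 lost and 7 gained a call, 23 changed sign without a call and 1 reversed. No paired analysis was possible because the series has 1 group. Read depth was not known, so what it limits could not be tested.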

Other observations

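The tests on the locus of fkh-10, on the stretch without regions around it, on the GC content of the strong X regions, on GC-matched draws at translation and energy genes and on their genes in the runs, and the counts in the next paragraph, were chosen only after the results were seen.

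Of 18 sls-2 genes, for spliced leader 2 RNAs, 6 had a relaxed or IDR region at the start, and 4 of these were bound, with no test of enrichment; the regions of sls-2.1 and sls-2.4 also lay at H41C03.3 and egg-5. IDR regions on chromosome X were at promoters less often than those on autosomes, 39.6% against 51.6% (Fisher's exact test, p = 1.4e-06). The background leaned the same way. On chromosome X 2529 of its 3442 regions lay away from promoters, while 5470 of all 17154 lay at them. Whether the gap is larger in IDR regions than in the background was not tested. The GAGA repeat, at 20.5% of other IDR regions, was at 3.57% of the 56 regions at ribosomal protein promoters (Fisher's exact test, p = 0.000573). Of the 60 bound snoRNA genes, 17 were reached by a region at a ribosomal protein promoter.

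The runs on chromosomes I and X, of 40.3 and 35.7 kb in the pooled list, are near the length of a fosmid insert. A candidate explanation is extra DNA copies of these segments in the animals. Only runs of at least 30 kb were kept, and the run on chromosome I was 54191 bp long in replicate 2. The length is therefore not evidence for this explanation. Summits in the runs were at promoters no more often than the bases of the runs, 30.6% (exact interval 22.5 to 39.6) against 28.4% (exact binomial test, p = 0.614). The preference of regions of like signal elsewhere would give 44.98%. However, the runs were picked for closely spaced regions, whose summits could spread over the bases whatever the cause. Adjacent summits are also not independent, so the test does not decide for extra copies. Extra copies of the fkh-10 locus are argued against as the source of the runs, since fkh-10 lies 4554 kb from the run on its chromosome, while the 0 pooled regions within 20 kb of it (median of 8 in 10000 random windows) leave open whether the libraries carried copies, which a control from the same strain would cancel. fkh-10 lay in 56.3 kb without a summit in any relaxed list, the fourth longest such stretch, and 0.444% of the genome lies in stretches as long. The 0 regions within 20 kb already imply a long stretch, so this value is not separate evidence. Such a stretch could arise if the control carried extra copies of the locus and the libraries did not. A construct other than the labelled one stays open, as do other reasons for the 3 longer stretches, and no biological explanation was tested.

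The 9 strong regions of chromosome X away from promoters may be recruitment sites of the dosage compensation complex, which loads onto the X chromosome at sequences with the motif core GCGCAGGG. The core lay within 100 bp of 5 of the 9, of 7 of 20 such X regions among the 100 strongest against 2 of the other 80, and of 3.75% of all X IDR regions away from promoters (12 of 320) against 0.120% of autosomal ones (1 of 834; Fisher's exact test, p = 1.73e-06). It was also more frequent at X promoters (5 of 210 against 1 of 889; Fisher's exact test, p = 0.00124), where the mean signal was 67.5 against 68.3 on autosomes (permutation test, p = 0.712). GC content stays open: the 9 windows had 39.5% GC ± 5.27 (SD) against 42.6% ± 6.61 in the other 311 (permutation test, p = 0.1597). GC matching, the test planned first, left X regions away from promoters stronger than autosomal ones (permutation test, p = 0.0245) but decided nothing. Mean GC was alike before it, at 42.5% and 42.6%, and the X regions included the 9, which were picked for their signal. The other 311 had a mean signal of 64.5, against 64.6 for all 834 autosomal regions, their strongest included. With adjustment over the tests of the core and the full motif, the core's p was 5.2e-06 away from promoters and 0.00248 at them. Within chromosome X, the core was at 12 of 320 IDR regions and 7 of 2529 other relaxed regions away from promoters (adjusted exact p = 4.84e-07). The full motif, which holds the core, was at 2 of 320 X regions against 0 of 834 autosomal ones (adjusted exact p = 0.0921). This did not pass the test. At promoters the full motif was at 0 of 210 and 0 of 889. The 2 of 320 compared with 0 of 2529 other relaxed X regions away from promoters (adjusted exact p = 0.0189). The core could account for part of the strong regions. It was absent from 308 of the 320, but only exact matches within 100 bp were sought, so this does not exclude recruitment sites there. Whether the tagged protein or open chromatin gives the signal stays open.

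Regions at translation and energy genes could reflect binding through the forkhead consensus, but the test left this open. At promoters of the ribosomal protein, translation factor, chaperone and respiration lists, RTAAAYA was in 15 of 102 windows (14.7%), within the range of GC-matched draws (7.84 to 20.6%, 10000 draws in the manner of a permutation test, p = 0.9499). At ribosomal protein promoters alone it was in 4 of 56 (7.14%), against a median of 14.3% in such draws (permutation p = 0.192) and 23.2% of a single GC-matched set (Fisher's exact test, p = 0.0328). The runs of regions are argued against as the cause, since 0.943% of the bound genes of the 4 lists (1 of 106) had a region in them; the test planned first, in which all 4 stayed called without the runs, decided nothing, as it removed at most 1 gene per list. Strong signal at highly transcribed genes without a target protein was not tested, because a control with untagged animals was not analysed here.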
